A study of Mus musculus with 6 samples.

How the data were processed

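Gene expression was measured on 6 Illumina bead arrays, 2 for each of 3 groups of mouse cells: pluripotent stem cells induced with recombinant proteins (piPSC), fibroblasts from embryonic day 13.5 embryos that carry a green fluorescent protein gene under the Oct4 promoter (OG2-MEF), and embryonic stem cells of the R1 line (ES). Per the labels' protocols, biotin-labelled cRNA was made from 500 ng of total RNA per sample, and embryonic stem cells were kept on irradiated fibroblast feeders with serum and leukemia inhibitory factor. The labels call the 2 arrays of a group biological replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these samples, part of which may be technical. The number of arrays limits the precision.

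The deposited table of 25697 probes held a raw intensity per probe and array on a linear scale, not normalized between arrays, and no value was at or below 0. The deposited detection p-value beside each intensity, per the file headers, moved in steps of 1 in 798 in the values. With probes ordered by the intensity of its own array, it did not rise between neighbouring probes in 100% of cases, ties included. The authors' deposited series matrix held log2 values, whose scale was found by recomputing them: quantile normalization of the log2 intensities with no background correction gave the same values within 0.0012. Each column of that matrix had a median of 5.89, and no centring of genes was found. Scanner, its software and any background subtraction by it were not given in the sources used here.

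For the values reported here, the intensities were background-corrected with normexp using the detection p-values, given an offset of 16, quantile-normalized and taken to log2 (neqc in limma 3.58.1, R 4.3.3). Probe symbols were updated through Entrez identifiers or accessions to the gene table of assembly GRCm38.p6, which was used for names and chromosomes only. Of the probes, 23978 had 1 symbol (23962 through the Entrez identifier, 9 through the accession and 7 from the array's own table), 0 had several and 1719 had none and were left unnamed. A probe was kept where its detection p was under 0.05 on both arrays of at least 1 group, and a gene with several probes was represented by the probe with the highest mean over the 6 arrays, which left 10748 genes. Where the median change of a named gene's other kept probes moved less than 2-fold the same way, that median is given.

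Differences between groups were tested with limma (lmFit and eBayes) in 1 fit of 3 group means with 3 residual degrees of freedom and a prior of 3.33, followed by Benjamini-Hochberg adjustment within each of the 3 comparisons. The fit uses 1 spread per gene for all groups. Between the 2 arrays of a group, the SD of the difference over genes was 0.57 for ES, 0.204 for piPSC and 0.188 for OG2-MEF. P-values of comparisons with ES may therefore be too small. Where the ES arrays differ, those of piPSC against OG2-MEF may be too large. A gene counted as changed at an adjusted p under 0.05 and a fold of at least 2. All gene p-values are limma's adjusted p, SE is the moderated standard error of a log2 fold change, SD is taken over the 2 arrays of a group, and n is 2 per group unless stated. A gene not above background on either array of the dimmer group is given as "at least N-fold": the brighter group's mean against the mean, over the dim group's arrays, of the higher of the lowest detected signal and the probe's own signal. Its fitted log2 fold change is no bound.

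Of 27 gene lists fixed before the data were examined, 26 had at least 3 tested genes and were tested with camera at its preset correlation of 0.01, adjusted over the lists of 1 comparison, with an estimated correlation as a check. The lists covered reprogramming factors, naive and primed pluripotency, the 2-cell-embryo-like state, fibroblast, epithelial, germ cell, endoderm, mesoderm, neural, trophoblast, macrophage, endothelial and muscle genes, Hox genes, imprinted genes and the Dlk1-Dio3 cluster, sex-linked genes, interferon response, p53 and cell cycle inhibitors, DNA replication, DNA methylation and Polycomb, glycolysis, oxidative phosphorylation, ribosomal proteins, stress, and LIF and BMP targets. The genes named in the text follow a rule that was also fixed then: per comparison the 10 largest changes each way among changed genes, up to 4 members of each list with the largest absolute change, and always Pou5f1, Sox2, Klf4, Myc, Nanog, the sex-linked genes and the Dlk1-Dio3 genes. Changes shared by comparisons against the same fibroblast arrays are set beside 100 simulations of unchanged groups and beside the overlap of independent lists. With 2 fibroblast arrays in all, these controls were not split.

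Alternatives covered the authors' matrix, the background offset, the scaling between arrays, the filter on dim probes, the choice of probe, the fold threshold, a test against that fold (treat), an intensity trend with robust priors, a fit of each pair of groups, the set test (fry), the replicate number as a block, and leaving out each array in turn. Array quality weights and gene lists under median scaling were added after the data were seen. The procedures were tested on simulated arrays. Of genes given a log2 change of 2, they recovered 98.5% for piPSC against OG2-MEF, 100% for ES against OG2-MEF and 95.5% for piPSC against ES, and they called 2 of 11077, 8 of 11085 and 12 of 11219 unchanged genes in the same order. The simulated noise was alike for all probes of a group, with no probes that lost signal on a single array. Changes were given only to genes of middle to high signal. These rates therefore do not describe dim genes or probes that behave differently on the ES arrays.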

Results

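Array signals were compared between protein-induced pluripotent stem cells (piPSC), the fibroblasts OG2-MEF and ES cells, with 2 arrays per group. Total signal was 15851013 and 15690377 on the piPSC arrays, 19393092 and 19598206 on the OG2-MEF arrays, and 14076530 and 13019817 on the ES arrays. Between 50.71% and 52.41% of probes were above background on the first 5 of these arrays, and 46.87% on ES replicate 2. Across 10748 genes, which are not independent replicates, Pearson's r between the arrays of a group was 0.9966 for piPSC, 0.9972 for OG2-MEF and 0.9731 for ES. ES replicate 2 was more than 2-fold below ES replicate 1 for 495 genes and above it for 27. Each piPSC array correlated with ES replicate 1 at 0.9724 or 0.9745 and with ES replicate 2 at 0.9313 or 0.9335. Because ES replicate 2 stood apart, counts and selected values without it are given beside the comparisons with ES. Leaving it out does not remove probes that were dim on both ES arrays while another probe of the gene was not. For example, a probe of Usp18 lay at 4.39 and 4.41 on the ES arrays and at 9.36 and 9.09 on the piPSC arrays. The probe used for this gene lay at 8.96 and 9.04 on the ES arrays.

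The series title states that pluripotent cells were made with recombinant proteins, and the comparison of piPSC with OG2-MEF asks how the induced cells differed from fibroblasts. Genes of the pluripotency network were high in piPSC and low or not above background in OG2-MEF. Pou5f1, which encodes the transcription factor Oct4, was at least 452-fold higher in piPSC (adjusted p = 2e-06), and Nanog, another core factor of the network, was 310-fold higher (log2 fold change 8.28, SE 0.14, adjusted p = 6.6e-07). Most genes of the fibroblast list fell (31 of 35). Over all genes tested, Col2a1, which encodes the collagen of cartilage and is on none of the lists, had the largest decrease, with a log2 fold change of -7.20 (SE 0.15, adjusted p = 9.2e-07). Of the 10748 genes, 4454 changed (41.4%), with 2150 higher and 2304 lower in piPSC.

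All 32 tested genes of the pluripotency list rose, with a median log2 fold change of 5.46, or 5.13 with the genes not above background in fibroblasts set at their bound (camera, adjusted p = 9.7e-16). That p was 0.061 with an estimated correlation, and none of the camera calls in any comparison held with one. The estimate for this list was -0.024, below the preset 0.01, so a stronger correlation between its genes is not what raised the p. The check's 3 degrees of freedom leave it little power. For other lists called in this comparison the estimate exceeded the preset, so their preset p may be too small. It was 0.12 for fibroblast, 0.13 for Hox, 0.15 for germ cell, 0.16 for DNA methylation and Polycomb and 0.42 for neural genes. The epithelial (-0.0087) and ribosomal protein (-0.0062) lists lay below the preset. Dppa5a, a gene of early embryos and ES cells, rose by 9.87 on the log2 scale (SE 0.12). Its OG2-MEF signals of 5.03 and 5.00 lay at the lowest detected signals of those arrays, 5.013 and 5.015. This change is therefore close to a bound. Fbxo15 was at least 411-fold, the nuclear receptor gene Esrrb at least 397-fold and the zinc finger gene Sall4 at least 239-fold higher. Rhox5, Wfdc2, Saa3 and Dppa4 completed the 10 largest increases, at least 419-fold, 325-fold, 301-fold and 192-fold. Among the reprogramming factors, Sox2 was at least 19.7-fold higher (adjusted p = 5.1e-06) and Klf4 4.68-fold higher (log2 fold change 2.23, SE 0.12, adjusted p = 1.7e-05), while Myc differed by -0.52 (SE 0.44, adjusted p = 0.32). With Pou5f1, 3 of these 4 genes rose (median 3.56, camera adjusted p = 0.043, and 0.25 with an estimated correlation). The reprogramming list's camera p was 0.051 without ES replicate 2.

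Other genes of early embryos, germ cells and epithelia rose with them. In the list of primed pluripotency, 6 of 9 genes rose and 1 fell (camera adjusted p = 0.043, 0.22 with an estimated correlation), among them Dnmt3b (5.31, SE 0.13) and Otx2 (at least 18.8-fold). The 2-cell-like list had 5 of 6 genes higher, with Zscan4c at least 16.3-fold and Tcstv3 at least 9.72-fold up (adjusted p = 0.0035, 0.22 with an estimated correlation). Of 15 germ cell genes, 12 rose, led by Tex19.1 (at least 167-fold) and Dazl (at least 43.4-fold), an RNA-binding protein of germ cells (adjusted p = 8.2e-06, 0.22 with an estimated correlation). Of 19 epithelial genes, 12 rose and 1 fell (adjusted p = 0.0035, 0.22 with an estimated correlation), and E-cadherin (Cdh1) was at least 33-fold higher.

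Fibroblast genes fell as a group: 31 of 35 were lower and 2 higher over all genes tested, and 32 were lower adjusted over the list alone (median -2.19, camera adjusted p = 1.3e-08, 0.22 with an estimated correlation). Tagln, a smooth muscle and fibroblast cytoskeletal gene, changed by -5.07 (SE 0.18), Thbs1 by -4.73 (SE 0.32) and the growth factor receptor gene Pdgfrb by -3.09 (SE 0.16). Dcn, a matrix proteoglycan gene on the same list, moved the other way, by 3.41 (SE 0.13). Hox genes, which pattern the body axis, were lower for 17 of 22 and higher for 1 (median -2.30, adjusted p = 2.9e-05, 0.22 with an estimated correlation), for example Hoxa5 at -4.91 (SE 0.16). Muscle genes were lower for 7 of 13 and higher for 1 (adjusted p = 0.0049, 0.22 with an estimated correlation). Myl1 was at least 71.8-fold lower, although the gene's other probe changed by -1.03, and Acta1 changed by -5.95 (SE 0.24). Of 6 neural genes, 4 fell and 0 rose, among them Nes at -4.20 (SE 0.16) and Ncam1 at -4.64 (SE 0.26). Camera's adjusted p for this list was 0.017, or 0.31 with an estimated correlation and 0.084 with no detection filter. After Col2a1, the largest decreases outside these lists were Gjb2 (-6.87), the imprinted Dlk1 (-6.34), Igfbp5 (-6.32), Sema3a (at least 48.3-fold lower), Il11 (-5.65), Cxcl12 (-5.57) and Tnfrsf11b (-5.46).

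**Figure D1:**
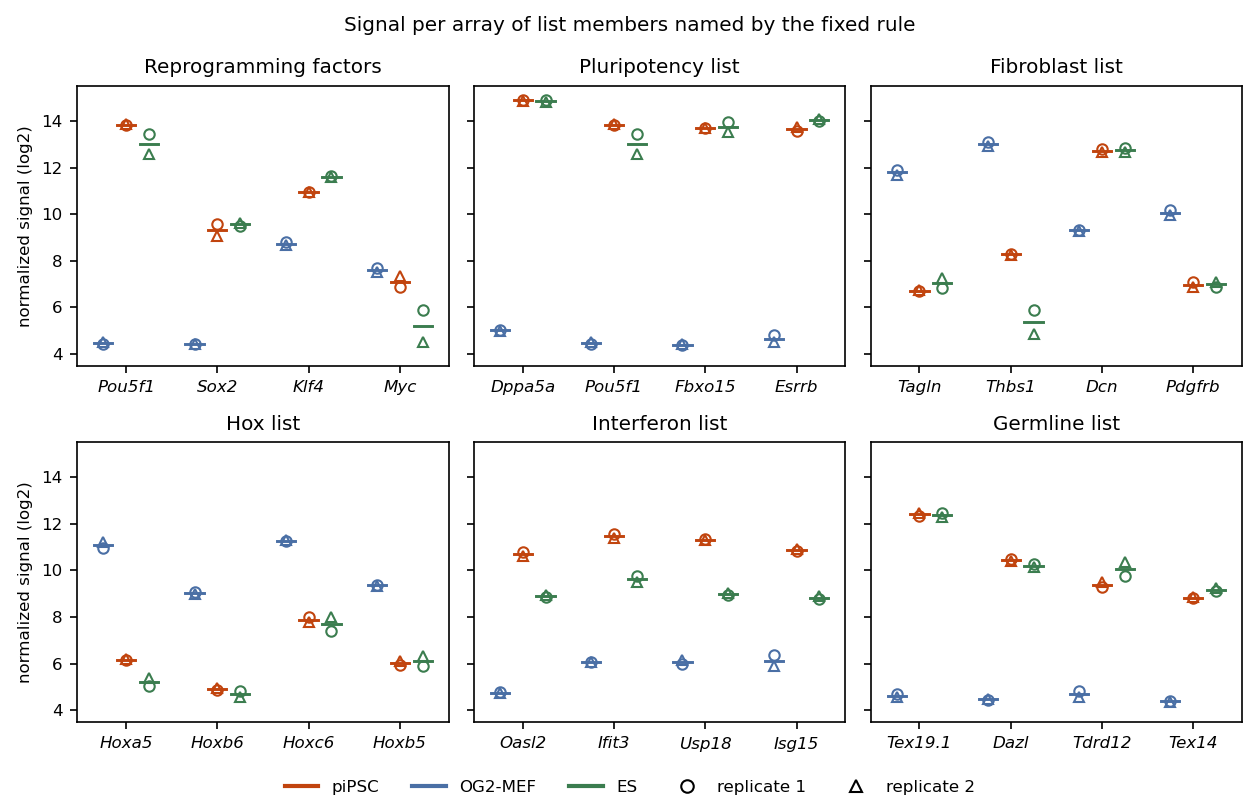
Normalized log2 signal (y axis) of the members of 6 gene lists chosen by the fixed rule for piPSC against OG2-MEF (x axis), with a circle or triangle for each of the 2 arrays of a group and a bar at their mean. Pou5f1, Dppa5a and Fbxo15 lie near the floor in OG2-MEF and high in both piPSC and ES, Thbs1 lies between ES and OG2-MEF in piPSC, and the 4 interferon genes are higher in piPSC than in ES.

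Genes of the interferon response, of DNA replication and of chromatin were higher in piPSC than in fibroblasts. In the interferon list, 20 of 26 rose and 0 fell (median 2.14, camera adjusted p = 2.3e-07, 0.16 with an estimated correlation). Usp18, which removes the ubiquitin-like protein Isg15, rose by 5.26 (SE 0.13), Isg15 by 4.76 (SE 0.18), Ifit3 by 5.41 (SE 0.15) and Oasl2 was at least 51.9-fold higher. Of 28 replication genes, 21 rose and 1 fell (median 1.99, adjusted p = 1.4e-06, 0.21 with an estimated correlation), including the helicase gene Mcm2 (2.55, SE 0.14) and Mcm10 (2.86, SE 0.16). Of 15 genes of DNA methylation and Polycomb, 10 rose and 0 fell (adjusted p = 0.00035, 0.22 with an estimated correlation). Dnmt3l, a cofactor of DNA methylation in germ cells, was at least 121-fold higher. In the oxidative phosphorylation list, 6 of 38 genes rose and 0 fell (median 0.55, adjusted p = 0.00027, 0.22 with an estimated correlation), and in the ribosomal protein list 1 of 50 rose, Rpl4 (median 0.25, adjusted p = 0.045, 0.22 with an estimated correlation). The ribosomal call ended without piPSC replicate 1 (0.097) or replicate 2 (0.058), and Rpl4 fell short of 2-fold under median scaling (0.76) and without OG2-MEF replicate 1 (0.98). The medians of both lists lay above the median of all genes, 0.02, which moved to -0.182 when the arrays were scaled to the same median.

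The other lists did not pass camera in this comparison: endoderm (3 higher and 7 lower of 13, adjusted p = 0.12), mesoderm (2 and 1 of 6, 0.44), trophoblast (5 and 1 of 7, 0.14), macrophage (1 and 4 of 9, 0.32), endothelial (4 and 2 of 8, 0.28) and glycolysis (4 and 1 of 17, 0.077, but 0.049 without OG2-MEF replicate 1 and 0.022 with no detection filter). The counts adjusted over the list alone were the same as over all genes for every list here except the fibroblast list. In the macrophage list Laptm5, a lysosomal membrane protein gene, rose by 5.24 (SE 0.14) while Cd14 changed by -1.46 (SE 0.15). Scaling to the same median moved the split of changed genes to 1678 higher and 2875 lower.

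The comparison of ES with OG2-MEF gives the difference between fibroblasts and an established pluripotent line, measured on the same arrays. ES cells carried high signals for the same kind of genes. Esrrb was at least 521-fold, Fbxo15 at least 427-fold and Pou5f1 at least 257-fold higher than in fibroblasts (adjusted p = 2.4e-06 for Pou5f1). Dppa5a rose by 9.84 (SE 0.12), from fibroblast signals near background, and Nanog by 8.41 (SE 0.14). Trh, the gene of thyrotropin-releasing hormone, was at least 325-fold higher. Thbs1, a secreted matrix glycoprotein gene, changed by -7.64 (SE 0.32), Col2a1 by -7.76 (SE 0.15) and Msn, which links the membrane to actin, by -6.46 (SE 0.54; -5.50 without ES replicate 2). Of the 10748 genes, 5020 changed (46.7%), with 2696 higher and 2324 lower in ES cells.

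Of the 32 pluripotency genes, 31 rose and 0 fell (median 5.52, or 5.11 with bounds, camera adjusted p = 1.8e-12, 0.086 with an estimated correlation). Sox2 was at least 23.3-fold higher and Klf4 rose by 2.88 (SE 0.12), while Myc was lower by a log2 fold change of -2.41 (SE 0.44, adjusted p = 0.0025), or -1.71 without ES replicate 2. The fitted change of Sox2 was 5.13, and 4.01 without ES replicate 2, when another of its probes had the highest mean. The reprogramming list as a whole did not pass camera (3 higher and 1 lower of 4, adjusted p = 0.14). Germ cell genes rose for 13 of 15 (adjusted p = 2.3e-05, 0.25 with an estimated correlation), led by Tex19.1 (at least 165-fold) and Dazl (at least 36.5-fold). Epithelial genes rose for 12 of 19 and fell for 1 (adjusted p = 0.0057, 0.25 with an estimated correlation), with Cdh1 at least 46.1-fold up. Replication genes rose for 21 of 28 and fell for 1, Ccne2 (adjusted p = 3.3e-05, 0.25 with an estimated correlation). Of 38 oxidative phosphorylation genes, 12 rose and 0 fell (adjusted p = 0.00053, 0.25 with an estimated correlation), led by Ndufb10, a subunit of complex I (3.23, SE 0.18).

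In the interferon list, 14 of 26 genes rose and 1 fell in ES cells (median 1.55, adjusted p = 0.003, 0.25 with an estimated correlation). Usp18 rose by 2.94 (SE 0.13), although 1 of its 2 other probes changed by -0.30, and the class I histocompatibility gene H2-D1 was at least 6.02-fold higher. Oasl2 was at least 15-fold higher and Ifit3 rose by 3.56 (SE 0.15) on the probe used, but the other probes of these genes changed by 0.19 and -0.01. Of 15 genes of DNA methylation and Polycomb, 11 rose and 1 fell (adjusted p = 0.019, 0.4 with an estimated correlation, and 0.18 without ES replicate 1). The gene that fell was Rbbp7, a histone-binding subunit, at -4.47 (SE 0.86; -2.93 without ES replicate 2), with 8.05 on ES replicate 1 and 5.03 on ES replicate 2, and 1 of its 3 other probes changed by 0.45.

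Fibroblast genes were lower for 32 of 35 and higher for 2 (median -2.35, adjusted p = 5.6e-10, 0.25 with an estimated correlation). Vim, the intermediate filament gene of mesenchymal cells, changed by -4.60 (SE 0.63), or -3.47 without ES replicate 2, and Timp3 by -3.79 (SE 0.15). Hox genes were lower for 18 of 22 and higher for 1 (adjusted p = 4e-05, 0.28 with an estimated correlation), with Hoxa5 at -5.86 (SE 0.16). Muscle genes fell for 8 of 13 and rose for 2 (adjusted p = 0.015, 0.4 with an estimated correlation), and neural genes fell for 4 of 6 (adjusted p = 0.02, 0.4 with an estimated correlation, 0.13 with no detection filter and 0.055 without ES replicate 1). Phgdh, an enzyme of serine synthesis, was at least 46-fold lower, and the protease gene Capn2 changed by -6.11 (SE 0.85), or -4.57 without ES replicate 2. The ES arrays lay at 7.61 and 4.62, the latter not above background. The lists of primed pluripotency (4 higher and 1 lower of 9, adjusted p = 0.16, and without ES replicate 2 just under the threshold at a rounded 0.05), the 2-cell-like state (3 and 0 of 6, 0.14), endoderm (5 and 7 of 13, 0.2), mesoderm (2 and 1 of 6, 0.72), trophoblast (5 and 1 of 7, 0.14), macrophage (2 and 4 of 9, 0.36), endothelial (4 and 2 of 8, 0.55), glycolysis (4 and 2 of 17, 0.84) and ribosomal proteins (4 and 0 of 50, 0.36) did not pass. Under median scaling the 2-cell-like and ribosomal lists each passed (both 0.026). Counts adjusted over the list alone were the same for every list of this comparison.

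**Figure D2:**
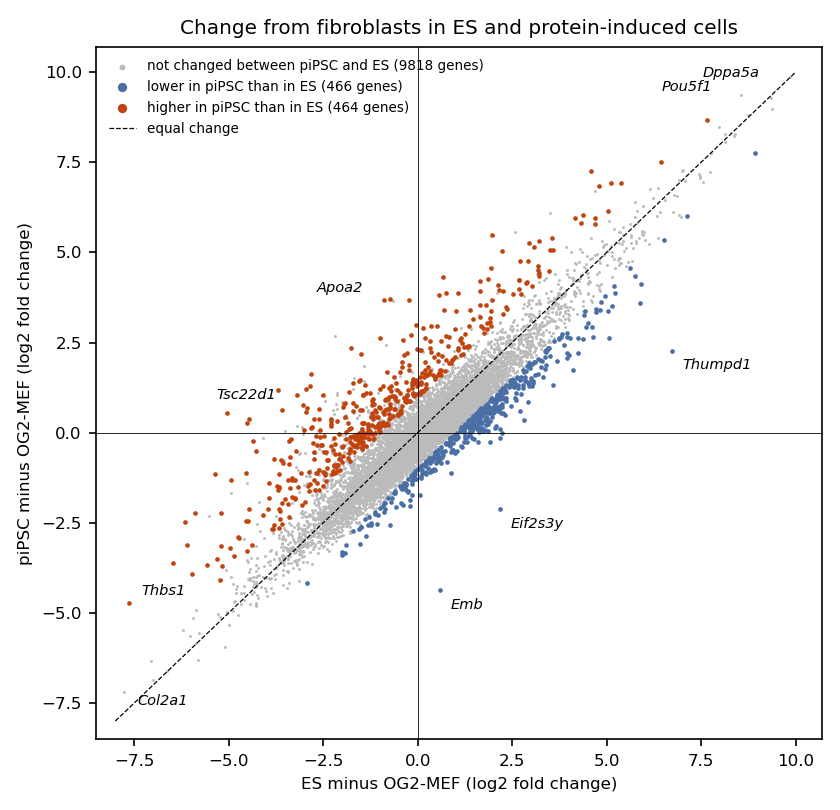
Log2 fold change of each of the 10748 genes in ES cells (x axis) and in piPSC (y axis), both against OG2-MEF, with the 464 genes higher and the 466 lower in piPSC than in ES coloured. Most genes lie along the dashed line of equal change (Pearson's r = 0.9066 across genes), and Emb, Thumpd1 and Eif2s3y lie below it.

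The changes of piPSC and ES cells against the fibroblasts were then set side by side. Against the same fibroblast arrays, 1837 genes were higher in both piPSC and ES cells, against 539.3 for independent lists, 1871 were lower in both, against 498.2, and 10 changed in opposite directions. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.9066, and 0.5 in simulated unchanged groups with shared controls. The covariance was 2.282 against 0.0227 simulated, a difference of 2.259, and 86.36% of genes had the same sign against 66.6% simulated. The shared controls may add to r, sign and overlap, but their simulated part of the covariance was small, 0.0227 beside 2.282. The simulated r and sign describe groups with no change, so they are no baseline for changes of this size. On a scale with OG2-MEF at 0 and ES at 1, the median gene lay at 0.873 in piPSC (quartiles 0.62 and 1.11, 4989 genes chosen on the replicate 1 arrays) and at 0.877 (0.657 and 1.04, 5269 genes chosen on the replicate 2 arrays), a value with no test. Without ES replicate 2, r was 0.935.

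The direct comparison of piPSC with ES asks where the induced cells differed from an established pluripotent line. On the probes used, Nanog differed by -0.13 (SE 0.14, adjusted p = 0.51), Pou5f1 by 0.82 (SE 0.26, adjusted p = 0.062), Sox2 by -0.24 (SE 0.19, adjusted p = 0.34) and Klf4 by -0.66 (SE 0.12, adjusted p = 0.015, under 2-fold). The other probes of Pou5f1 and Sox2 gave 3.75 and 2.10. Without ES replicate 1 or 2 that other Sox2 probe had the highest mean, and the difference was 2.59 or 1.56. Interferon response genes were higher in piPSC, for example Usp18 by 2.32 (SE 0.13, adjusted p = 5e-04) and Isg15 by 2.05 (SE 0.18, adjusted p = 0.0019). Emb, which encodes the membrane protein embigin, was lower in piPSC by a log2 fold change of -4.96 (SE 0.15, adjusted p = 7.3e-05). Of the 10748 genes, 930 changed (8.65%), 464 higher and 466 lower. Leaving out an ES array leaves 1 in its group, whose spread is then taken from the less variable piPSC and OG2-MEF pairs. Calls kept in such a fit therefore give no check of how the spread between ES arrays affects the count of changed genes. The count was 151 without piPSC replicate 1, 298 without piPSC replicate 2 and 1820 without ES replicate 1. It was 614 (401 higher and 213 lower) on the authors' matrix, and with every kept probe tested 1391 genes had a changed probe (862 higher and 547 lower, some of them both). Of 60 changed genes chosen by the naming rule, 41 lost their call without piPSC replicate 1, 30 without piPSC replicate 2, 14 without OG2-MEF replicate 1, 14 without OG2-MEF replicate 2, 6 without ES replicate 2 and 2 without ES replicate 1. Without a piPSC array these losses came from a higher adjusted p. Only Tcstv3 (0.95) and Mcm7 (0.72), without piPSC replicate 1, also fell under 2-fold. On the authors' matrix and with quantile normalization alone 8 genes lost their call (Tcstv3, Cldn3, Rhox6, Amn, Mcm7, Rpl21, Trib3 and Msx2), and under median scaling 8 (Rhox6, Snrpn, Apoe, Rpa2, Pfkl, Atp5o, Rpl21 and Id1).

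The 10 largest increases in piPSC over ES included genes whose ES arrays differed strongly from each other. Apoa2, an apolipoprotein gene, was at least 16.5-fold higher with both ES arrays not above background, and the elongation factor gene Eef2 rose by 4.22 (SE 0.18), with other probes at 4.40. Tsc22d1 rose by 5.58 (SE 0.31), but its other probes by 0.72, and Snrnp70 rose by 4.87 (SE 0.59). Rbbp7 rose by 4.86 (SE 0.86, 3.31 without ES replicate 2), with ES arrays at 8.05 and 5.03, while its 3 other probes changed by 5.36, 4.46 and -0.87. Eif3c (4.77, SE 1.14), Umps (4.45, SE 0.64), Gm8909 (4.44, SE 0.58), Hnrnpk (4.23, SE 0.87) and Gm5643 (4.23, SE 1.14) each lay lower on ES replicate 2 than on ES replicate 1, with Eif3c and Gm8909 not above background on the former. These 5 changes were 2.72, 3.31, 3.39, 2.67 and 2.20 without ES replicate 2, and that of Snrnp70 was 3.81. The other probes of Umps, Hnrnpk and Gm5643 changed by 0.33, -0.36 and 0.23. Over all genes with other kept probes, these changed at least 2-fold the same way for 71 of 147 genes higher in piPSC and 25 of 89 lower.

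After Emb, the largest decreases in piPSC were those of Thumpd1 (-4.46, SE 0.14) and the Y-linked translation factor gene Eif2s3y (-4.31, SE 0.12), with ES arrays at 10.38 and 10.44 and piPSC arrays at 6.10 and 6.09. Hps1 (-2.47, SE 0.22), Pglyrp1 (-2.45, SE 0.14), the transcription factor gene Sp5, a target of Wnt signalling (-2.28, SE 0.17), Cdx2, a regulator of trophoblast and gut (-2.25, SE 0.13), and the keratin gene Krt18 (-2.18, SE 0.26) followed. Chmp1a was at least 4.41-fold and Cit at least 3.83-fold lower, with neither piPSC array above background.

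In the interferon list, 15 of 26 genes were higher in piPSC than in ES and 0 lower (median 1.03, camera adjusted p = 2.2e-15, 0.1 with an estimated correlation). Without ES replicate 2, which leaves 1 ES array, the list's median was 1.13. A probe each of Usp18 and Ifit3 was dim on both ES arrays (4.39 and 4.41, 4.64 and 4.44). The probes used for these genes were not (8.96 and 9.04, 9.77 and 9.49). Loss of probe signal shared by both ES arrays was not tested for this list. Ifi35 rose by 2.17 (SE 0.33). Ddx58, which encodes the RNA sensor RIG-I, rose by 3.63 (SE 0.91), or 2.00 without ES replicate 2, with ES arrays at 8 and 4.80. In the 2-cell-like list, 3 of 6 genes rose and 0 fell (adjusted p = 9e-05, 0.31 with an estimated correlation): Tcstv1 by 2.72 (SE 0.12), Zscan4c by 2.62 (SE 0.51) and Tcstv3 by 1.12 (SE 0.21). Zscan4c lay at 7.28 and 5.56 on the ES arrays, and the change was 1.74 without ES replicate 2. Its call ended without either piPSC array (adjusted p = 0.12 and 0.092) or either OG2-MEF array (both 0.055), as did that of Tcstv3 (0.12 and 0.071, 0.055 and 0.056), which was also under 2-fold on the authors' matrix (0.99) and without ES replicate 1 (0.84). Glycolysis genes passed camera (median 0.39, adjusted p = 0.00017, 0.25 with an estimated correlation) with 2 of 17 higher, Hk1 at 2.22 (SE 0.44), or 1.59 without ES replicate 2, with ES arrays at 5.67 and 4.38, and Pfkl at 1.11 (SE 0.14), whose other probes changed by -0.19 and which was under 2-fold under median scaling (0.97). Adjusted over the list alone, 3 glycolysis genes were higher. Pfkp, also on this list, was not counted as changed over all genes. It differed by 4.89 on the probe used, with ES arrays at 9.85 and 4.65. Another kept probe of Pfkp gave 4.25, with ES arrays at 5.08 and 5.39. The fibroblast list also passed (median 0.25, adjusted p = 0.0088, 0.56 with an estimated correlation), with 2 of 35 higher, Thbs1 at 2.91 (SE 0.32) and Timp3 at 1.25 (SE 0.15, other probe 0.99). Without ES replicate 2 its adjusted p was 0.028, and without piPSC replicate 1 it was 0.063, which ends the call.

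Of the 32 pluripotency genes, 3 were higher and 2 lower in piPSC (median -0.07, mean 0.10, adjusted p = 0.25, and 0.049 without ES replicate 2). Dppa3, a maternal factor that protects DNA methylation in the zygote, rose by 2.05 (SE 0.15), Fgf4 by 1.56 (SE 0.15), and Tdgf1, a co-receptor of Nodal, changed by -1.40 (SE 0.22, other probe -0.63). Myc was higher by 1.89 (SE 0.44, adjusted p = 0.026), or 1.19 without ES replicate 2, with ES arrays at 5.91 and 4.5, and 1 of the 4 reprogramming factors changed (camera adjusted p = 0.58). Without ES replicate 1 the reprogramming list passed camera (adjusted p = 0.025). Of 9 primed pluripotency genes, 2 rose (adjusted p = 0.34), Nodal at 3.52 (SE 0.97), with ES arrays at 8.13 and 4.70, and Zic2 at 3.26 (SE 0.56), with 6.48 and 4.57. Leaving out ES replicate 2 gave 1.77 and 2.28. Germ cell genes were lower for 5 of 15 (adjusted p = 0.42), among them Mov10l1 (-1.68, SE 0.17) and Sohlh2 (-1.52, SE 0.24). Epithelial genes were lower for 3 of 19, Krt18, Krt8 (-1.60, SE 0.16) and Cldn3 (-1.40, SE 0.27), and adjusted over the list alone 1 was also higher (camera adjusted p = 0.8). The call of Cldn3 ended on the authors' matrix (-0.94), without either piPSC array (adjusted p = 0.12 and 0.086) and without either OG2-MEF array (both 0.057).

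**Figure D3:**
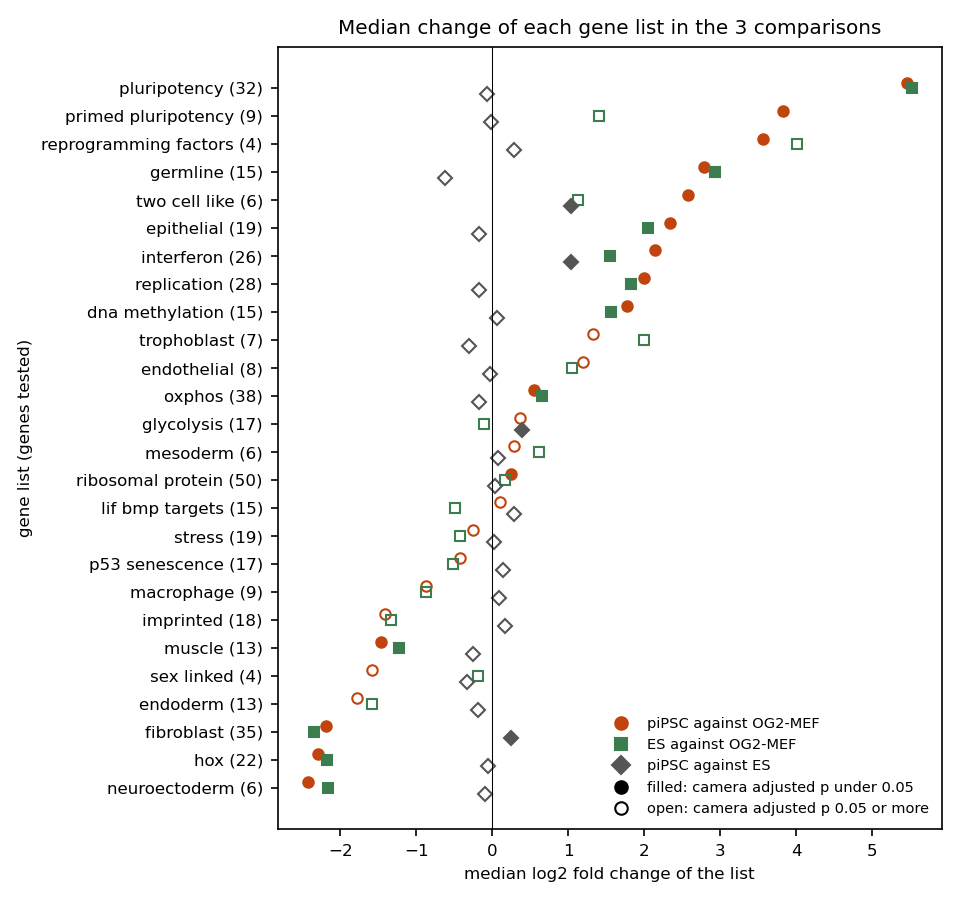
Median log2 fold change (x axis) of each of 26 gene lists (y axis, with the number of genes tested) in the 3 comparisons, filled where camera's adjusted p was under 0.05. The pluripotency list lies at 5.46 and 5.52 against OG2-MEF and at -0.07 between piPSC and ES, and the interferon list at 1.03 between piPSC and ES.

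No other list passed camera between piPSC and ES. In the trophoblast list 2 of 7 genes were lower (adjusted p = 0.22), Cdx2 and Rhox6 (-1.15, SE 0.17). Rhox6 was under 2-fold on the authors' matrix (-0.84), under median scaling (-0.89) and without ES replicate 2 (-0.94), and its call ended without either piPSC array (adjusted p = 0.081 and 0.072). The endoderm list had 1 higher and 1 lower of 13 (0.6), the mesoderm list 1 higher of 6 (0.21) and the muscle list 1 lower of 13 (0.69). The replication list had 2 higher of 28 (0.84, and 1 adjusted over the list alone), with a median of -0.17 and a mean of 0.10. The list of DNA methylation and Polycomb had 2 higher of 15 (0.1, and 0.0027 without ES replicate 1), oxidative phosphorylation 1 higher of 38 (0.69, and 0 adjusted over the list alone) and ribosomal proteins 1 lower of 50 (0.1). In the Hox (22 genes, camera adjusted p = 0.42), neural (6, 0.69), macrophage (9, 0.34) and endothelial (8, 0.61) lists 0 genes changed. The median of all genes lay at -0.175 in this comparison.

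The genes changed between piPSC and ES were also sorted by the side on which piPSC lay. There were 186 genes higher in piPSC than in both other cell types and 82 lower than in both, with Apoa2 and Gm8909 among the former and Emb and Eif2s3y among the latter. Independent lists would share 92.82 and 99.89 genes, but both comparisons use the same 2 piPSC arrays, so these values set no chance level. In 458 genes the piPSC mean lay between the other means, 163 of them higher and 295 lower in piPSC than in ES. Thbs1 was one of the former, at 8.31 on piPSC replicate 1, 13.09 on OG2-MEF replicate 1 and 5.91 on ES replicate 1. Genes apart from both numbered 63 without piPSC replicate 1, 109 without piPSC replicate 2 and 463 without ES replicate 1, and those between 65, 130 and 891. The numbers were 236 (182 higher and 54 lower) and 324 (141 and 183) without ES replicate 2. On the authors' matrix they were 166 (140 and 26) and 284 (138 and 146).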

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

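Array quality weights and the gene lists under median scaling were chosen after the data were seen, and the other alternatives before the data were examined. The direction and call of a gene list stayed in 251 of 260 settings and lists for piPSC against OG2-MEF, 254 of 260 for ES against OG2-MEF and 256 of 260 for piPSC against ES, and those of a named gene in 1117 of 1140, 1140 of 1150 and 1042 of 1210. These totals include lists and genes that were not called with all arrays. The list totals leave out the estimated correlation and fry. In the gene totals the authors' matrix and quantile normalization alone count as separate settings, although they gave the same counts of changed genes. The counts of changed genes were, in that order of comparisons, 2923, 3261 and 435 with probes detected on all 6 arrays, 4662, 5507 and 1391 (862 higher and 547 lower, some of them both) with every kept probe tested, 7321, 7868 and 2933 with no minimum fold, and 2651, 3173 and 72 when tested against a 2-fold change. The first setting tests fewer genes, the next one counts a gene if any probe changed, and the other ones change the threshold. For piPSC against ES the count was also 614 on the authors' matrix and with quantile normalization alone, and 519 with an offset of 50, and the cause was not tested. A fit of each pair of groups alone called 4524, 4974 and 681 genes, the last with 298 higher and 383 lower. Leaving out each array gave 4272 to 4559, 4799 to 5376 and 151 to 1820 changed genes. The lone array left in a group was assumed to vary like the others, although the ES arrays varied more than those of the other groups. Without ES replicate 1 the ES group rests on ES replicate 2 alone. Median scaling gave 1678 higher and 2875 lower genes for piPSC against OG2-MEF and 468 and 306 for piPSC against ES, against 401 and 213 on the matrix.

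Camera with an estimated correlation, a check with 3 degrees of freedom and little power here, called 0, 0 and 0 lists. For some of the lists called at the preset, such as fibroblast and Hox genes, the estimate was also above the preset. The set test fry, which does not compare a list with other genes, called 23, 20 and 10. Leaving out each array gave 14 to 16, 9 to 12 and 3 to 6 lists. The position of piPSC was 0.784 with genes chosen and measured on the same replicate 2 arrays, which by construction keeps their chance values. The correlation of fold changes ran from 0.853 without ES replicate 1 to 0.935 without ES replicate 2. Genes apart from both other groups numbered 166 on the matrix and with quantile normalization alone, and 63 to 463 with an array left out, and genes between them 284, and 65 to 891. Sox2 in piPSC against ES ran from -0.50 to 2.59 with an array left out, against -0.24 with all arrays. It was reversed without ES replicate 1 (2.59) and without ES replicate 2 (1.56), because another of its probes then had the highest mean. The deviations of same-numbered arrays correlated at 0.251 for OG2-MEF and ES, 0.06 for OG2-MEF and piPSC and 0.0101 for ES and piPSC. A replicate effect shared by OG2-MEF and ES therefore stays open. A fit with the replicate block called 4462, 5028 and 948 genes. In that fit the adjusted p of the reprogramming and primed pluripotency lists for piPSC against OG2-MEF was 0.052 and 0.055, and no other list or named gene changed its call. Array quality weights gave 4515, 5067 and 1055 genes. The chip as a block was not run, because the column names give no chip. Probes not above background in a group limit 949, 1134 and 117 of the changed genes to bounds.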

Other observations

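Of the tests in this part, those of lost probe signal and of feeder or differentiated cells in ES replicate 2 were chosen after the result was seen; so were the set of 163 genes, narrowed from 458 after its counts were seen, and the thresholds for chromosomes 13 and 14, set after the medians of whole chromosomes but before those of their parts were seen.

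Among sex-linked genes, Xist, the RNA that silences an X chromosome, lay at 9.22 on OG2-MEF replicate 1 and changed by -4.21 (SE 0.19) in piPSC and -4.33 (SE 0.19) in ES cells. The Y-linked Eif2s3y fell by 2.13 (SE 0.12) in piPSC and rose by 2.19 (SE 0.12) in ES cells against the fibroblasts. In piPSC 3 of the 4 sex-linked genes were lower than in OG2-MEF, Kdm5d by at least 1.66-fold, with Uty at -0.04 (adjusted p = 0.82). The fitted change of Kdm5d, -1.03 (SE 0.17), was under 2-fold on the authors' matrix (-0.67) and without OG2-MEF replicate 1 (-0.88). Camera's adjusted p was 0.059 there (0.018 with no detection filter), 0.82 for ES against OG2-MEF (1 higher, 1 lower) and 0.25 for piPSC against ES (1 lower). The hypothesis of 2 active X chromosomes in piPSC predicted a shift of at least 0.3 for X-linked against autosomal genes. The median shift from ES replicate 1 to piPSC was 0.03 (95% bootstrap interval -0.04 to 0.07, 337 genes), which argues against it. Against OG2-MEF it was -0.12 in piPSC and -0.12 in ES cells. A test of failed Y-linked probes was also written down and then dropped once this value had been seen, because X-linked probes say nothing about Y-linked ones.

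Of 18 imprinted genes, 5 were higher and 10 lower in piPSC than in OG2-MEF (camera adjusted p = 0.19), 5 higher and 9 lower in ES cells (0.14), and 2 were higher in piPSC than in ES (0.14), Gnas (3.65, SE 0.75; 2.32 without ES replicate 2) and Snrpn (1.02, SE 0.15, other probe 0.80; 0.91 without ES replicate 2 and 0.96 under median scaling). The call of Gnas ended without either piPSC array (adjusted p = 0.12 and 0.1) or either OG2-MEF array (both 0.059). The 2 tested genes of the Dlk1-Dio3 cluster moved in opposite directions: Dio3 rose by 2.70 (SE 0.15) in piPSC and 2.98 (SE 0.15) in ES cells, and Dlk1 changed by -6.34 (SE 0.20) and -7.05 (SE 0.20). Between piPSC and ES they differed by -0.28 (adjusted p = 0.19) and 0.71 (adjusted p = 0.045, under 2-fold). Stress genes had 7 of 19 higher and 6 lower in piPSC than in OG2-MEF (0.9), with a median of -0.26 and a mean of 0.20, 5 and 6 in ES cells (0.32), and 2 and 1 in piPSC against ES (0.21), where Atf4, a regulator of the amino acid response, rose by 4.14 (SE 0.28), Trib3 was at least 2.16-fold higher (fitted 0.87 on the authors' matrix) and Fos changed by -1.76 (SE 0.16). The list of p53 targets and cell cycle inhibitors had 4 of 17 higher and 4 lower in piPSC than in OG2-MEF (0.45), 2 and 6 in ES cells (0.16), and 1 higher between piPSC and ES (0.14), Sesn2 (2.45, SE 0.21). LIF and BMP targets had 3 of 15 higher and 2 lower in piPSC than in OG2-MEF (0.74), 4 and 4 in ES cells (0.55) and 2 higher in piPSC than in ES (0.1), Msx2 (at least 2.03-fold) and Id1 (1.12, SE 0.14). The fitted change of Msx2 was under 2-fold on the authors' matrix (0.88) and that of Id1 under median scaling (0.98), and both calls ended without piPSC replicate 1 (adjusted p = 0.057 and 0.065).

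The 495 genes more than 2-fold lower on ES replicate 2 than on ES replicate 1 may reflect signal lost by single probes. Over 169 of these genes with other kept probes, the other probes moved by a median of 0.07 of the main probe's change (95% bootstrap interval 0.03 to 0.19), against 0.84 (0.82 to 0.87) over 611 genes lower in piPSC than in OG2-MEF. Normalization is argued against, since at least 465 genes lay there under quantile normalization alone or median scaling. Differentiated or feeder cells are argued against as the cause, since enough of them to lower genes 2-fold would lower the pluripotency list alike, and it moved by -0.08 (-0.19 to 0.07, 32 genes) relative to all genes. A smaller share of such cells stays open, and so does loss of part of the transcripts. Where along each transcript the probes lie was not analysed here. The muscle and Hox lists both lay at 0.22 relative to all genes, but the fibroblast and endoderm lists at -0.08 and -0.09. Muscle and Hox medians were low, 5.75 and 5.63 on ES replicate 1 and 6.45 and 5.82 on ES replicate 2. The lowest detected signal was 5.043 on ES replicate 1 and 5.308 on ES replicate 2. The 0.22 of these dim lists is therefore no clear sign of such cells.

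Genes higher in piPSC than in ES but lower than in OG2-MEF, 163 in all, could come from fibroblasts left in the piPSC culture. Of the OG2-MEF signal over ES replicate 1, the median of these genes needed a share of 39.7% (31.8 to 47.7), while 9 fibroblast genes at least 8-fold higher in OG2-MEF than in ES replicate 1 reached 3.07% (0.858 to 4.59), with Vim at 4.59% and Timp3 at 10.8%. A fibroblast share is therefore argued against as the whole cause. Probe loss on the ES arrays cannot be told apart from a change in the transcripts, since other probes moved by 0.52 of the main probe's change (0.43 to 0.76, 53 genes), between the level set for loss and the 0.81 of genes higher in piPSC than in OG2-MEF.

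Genes of chromosomes 13 and 14 were higher in piPSC than in ES. Relative to the other autosomes the median against ES replicate 1 was 0.32 (0.27 to 0.38, 361 genes) on chromosome 13 and 0.29 (0.25 to 0.38, 338 genes) on chromosome 14. Both lay above 100% of 10000 random gene lists, while chromosomes 1 to 12, 15 to 19 and X lay between -0.05 and 0.03. Against ES replicate 2 the medians were 0.34 and 0.29, for which no random lists were drawn. A candidate explanation is a difference in copy number of whole chromosomes: with each chromosome split by gene order into 3 parts, all 6 parts were shifted, the lowest by 0.26 (0.17 to 0.35, 113 genes). From ES replicate 1 to replicate 2 the lower of the medians was -0.007 (-0.047 to 0.03), which argues against probe loss particular to ES replicate 2. Loss shared by both ES arrays cannot appear in this test and stays open. Against OG2-MEF, chromosome 13 lay at 0.07 in piPSC and -0.22 in ES cells and chromosome 14 at 0.33 and -0.02, which leaves open which cells differ.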
